A study of Mus musculus and Homo sapiens and Rattus norvegicus with 24 samples.

How the data were processed

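MicroRNA levels were measured on 24 two-color arrays. RNA of each sample carried a green dye, and a red-labeled mix of synthetic DNA oligos, used by the authors only to check hybridization, was added to each array. Per the labels, the samples were cultured hippocampal neurons of newborn rats and the hippocampus and cerebellum of adult mice, given morphine, fentanyl or a control treatment for 3 days. They also state that a replicate pooled several animals, that the replicates of a group came from experiments on different days, and that 9 mice were treated, so the number of animals behind a mouse array is unclear. Cultures were kept for 3 weeks and received morphine at 1 µM or fentanyl at 10 nM. Mice were 6 to 8 weeks old and received the drugs from an implanted pump at 12 µg per hour for morphine and 0.31 µg per hour for fentanyl over 72 hours, and control mice received saline. The doses thus differed between the drugs and between cultures and mice.

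Per the file headers, the authors quantified each scan with BlueFuse and averaged the spots of each probe name, so that 4704 spots gave 1147 rows per array. The deposited amplitude of each channel is a fluorescence intensity on a linear scale, neither scaled between arrays nor accompanied by a local background. The deposited probability that a spot carries signal is a fraction between 0 and 1. The deposited series values are a ratio: checked against the scanner files, each equals the green intensity divided by the 75th percentile of its array, within rounding. The headers also placed the scans in 8 sessions, named here A to H. The session letters are used because the groups were spread unevenly over them.

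Of the probes, 713 named a human, mouse or rat microRNA and were analyzed. Of these, 286 named a human microRNA only, and what they detect in mouse or rat samples was not tested. Probes naming only microRNAs of worms (name prefixes cel, cbr or sme), 111 in all, served as background. A probe counted as above background on an array where its green amplitude exceeded the 95th percentile of the worm-only probes. The green amplitude was background-corrected by the normexp method with an offset of 50, put on a log2 scale and quantile-normalized between the arrays of each fit. Probes above background on all arrays of at least 1 group were kept. Groups were compared with moderated linear models in limma 3.58.1 under R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the kept probes, with a threshold of 0.05. The arrays of a tissue shared 1 estimate of the spread, so the single array of fentanyl-treated cerebellum was assumed to vary like the other groups. The comparison of cerebellum with hippocampus used all 15 mouse arrays with treatment in the model. Differences between tissues in a drug response were tested as interaction terms. In all, 13 comparisons were made. All differences are on the log2 scale and are given with the standard error (SE) of the model.

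Where a probe was above background on no array of one group, a fold was given only as a lower bound, computed against the background threshold. No fold was given where both groups were below background. Values of a single session were computed where it held arrays of both groups, and a model with scan session as a block was fitted beside each comparison.

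The probes named in the text followed a rule: the 10 largest rises and 10 largest falls among the probes past the threshold, or, where fewer than 10 passed, up to 5 probes with the smallest p in each direction, reported as values that did not pass. In addition, 16 lists of microRNAs were fixed: neuronal, activity-regulated, the Dlk1-Dio3 cluster, the let-7 family, the miR-17-92 family, astrocyte-enriched, oligodendrocyte-enriched, microglia and leukocyte, erythroid, vascular, choroid plexus and ependyma, muscle, hindbrain, epithelial, low in brain, and microRNAs that the literature links to opioid receptors. miR-190 was named because the paper of the study is known to report it, so it was chosen on these samples. Lists with at least 3 kept probes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The rule, the lists, the tests and the alternatives were fixed before the data were examined, except for those named in the closing section as chosen later.

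The alternatives were no background correction, scaling by the 75th percentile, cyclic loess, no filter on dim probes, a filter on every array, array quality weights, the authors' deposited values, the replicate number or animal pool as a block, scan session as a block, the 2 compared groups alone, and leaving out each array in turn. A filter on the BlueFuse probability of at least 0.5 and fits without the arrays of session H, without the rat arrays numbered 3 and with session C alone were added after the data were seen. The replicate numbers paired the rat arrays: all 9 pairs of the same number and different treatment correlated above 0.1 across probes (median r = 0.679). These are correlations across probes, which are not independent replicates. In hippocampus 5 of 9 such pairs exceeded 0.1, and the 2 pairs in cerebellum are too few to tell. Most of the rat pairs also shared a scan session, so replicate number and session are largely confounded. The values given for rat neurons come from the model without a block, so their SE includes the spread between experiments. With the replicate number as a block no rat drug comparison called a probe.

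For arrays, precision is limited by their number. The models were tested on simulated data made from the probe means and residual spreads of each comparison, with 10 probes changed by 1 and 10 by 2 on the log2 scale in each of 10 draws. The share recovered is given in the closing section.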

Results

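The study asked how the opioid agonists morphine and fentanyl affect microRNA levels in neurons. Levels were measured in cultured hippocampal neurons of newborn rats and in the hippocampus and cerebellum of adult mice. The 24 arrays comprised 9 of rat neurons and 9 of mouse hippocampus, with 3 arrays each for control, morphine and fentanyl. The 6 cerebellum arrays comprised 2 of control, 3 of morphine and 1 of fentanyl. Between 9.82% and 23.7% of the 713 mammalian probes were above background on an array, that is 70 to 169 probes. The ratio of green signal to background ranged from 6.38 on the array of hippocampus control 3 to 44.6 on that of rat control 2. The number of arrays limits the precision of every value.

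In cultured rat neurons, no microRNA passed the threshold between morphine-treated and control cultures. let-7i, of a family known for its role in developmental timing, gave a log2 difference of -0.51 (SE 0.29), with -0.17, -0.28 and -1.09 in scan sessions D, E and G. The rat-sequence probe of miR-124a, which is abundant in neurons, gave 0.44 (SE 0.26), with 0.04, 0.17 and 1.12 in the same sessions. The mouse-sequence probe of miR-124a gave -9.6e-05 (SE 0.21). let-7b gave -0.28 (SE 0.20) and miR-376a of the Dlk1-Dio3 cluster 0.45 (SE 0.36). Of the 11 let-7 probes, 6 were positive and 5 negative, and of the 8 neuronal probes 3 were positive and 5 negative. limma called 0 of 72 probes, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 1. Of the 5 lists tested, 0 were called.

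Fentanyl-treated rat neurons likewise gave no microRNA past the threshold against control. let-7d was 0.46 higher (SE 0.20), with 0.14 and 0.37 in sessions D and E, and miR-721 gave 0.80 (SE 0.42), with 0.18 and -0.12. miR-184, which neuronal activity regulates, gave -0.62 (SE 0.51), without a value on fentanyl 3. The 8 astrocyte-enriched probes had a median of -0.18, 6 of them negative, and came nearest of the lists to the threshold, with an adjusted p of 0.0512 (adjusted p = 0.411 with an estimated correlation). With the deposited values their median was 0.03. limma called 0 of 72 probes, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.928. The median of all probes was 0.12, and -0.06 with 75th percentile scaling.

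Set directly against morphine, fentanyl-treated rat neurons had a log2 difference of 0.52 (SE 0.19) for miR-23a, an astrocyte-enriched microRNA, with 0.64 and 0.37 in sessions D and E. The rat-sequence miR-124a probe gave -0.64 (SE 0.26), with -0.11 and -0.31, while the mouse-sequence probe gave -0.15 (SE 0.21). miR-23a and the rat-sequence miR-124a probe were the 2 of 72 probes with an unadjusted p under 0.05. After adjustment limma called 0 (adjusted p = 0.982 for both). Of the 5 lists, 0 were called. The drugs were given to the cultures at different concentrations, 1 µM and 10 nM.

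miR-190, which the paper of the study is known to report, was below background on all 9 rat arrays. Its green amplitude was 962 ± 428 (SD, n = 3) in control, 963 ± 383 (SD, n = 3) in morphine and 641 ± 164 (SD, n = 3) in fentanyl cultures. The mean background thresholds of these groups were 3166, 2769 and 2457, so no fold is given. These thresholds lie far above the median amplitude of the worm-only probes, 459 to 676 on the rat arrays. The label below background thus depends on the brightest worm-only probes and does not show that miR-190 was absent. In mouse, miR-190 was above background on 2 of the 3 hippocampus morphine arrays and on none of the other mouse arrays. miR-339, another microRNA linked to opioid receptors, was above background on none of the 24 arrays.

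In mouse hippocampus, morphine for 3 days moved no microRNA past the threshold. miR-29a, an astrocyte-enriched microRNA, gave -0.56 (SE 0.27), with 0.08 in session A and -0.62 in session C, and miR-29c gave -0.42 (SE 0.26). With the deposited values, on which the median of all probes was 0.49, both turned positive, 0.16 and 0.17. miR-451, abundant in red blood cells, gave 0.57 (SE 0.35), with -0.23 and 0.74 in sessions A and C. All 5 choroid plexus probes were positive (median 0.41, adjusted p = 0.0641) and 15 of 19 Dlk1-Dio3 probes were positive (median 0.21, adjusted p = 0.459), the latter with a median of -0.01 under 75th percentile scaling. limma called 0 of 133 probes, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.852. Of the 8 lists, 0 were called.

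Fentanyl-treated hippocampus showed larger differences from control, none of which passed the threshold over all arrays. miR-363-5p, of the miR-17-92 family, gave 1.67 (SE 0.50), miR-495 of the Dlk1-Dio3 cluster 0.81 (SE 0.28) and miR-103, linked to opioid receptors, 0.58 (SE 0.24). Lower signals, each below background on fentanyl 2 and 3 so that the sizes are uncertain, were found for miR-136 of the Dlk1-Dio3 cluster at -1.26 (SE 0.48), the astrocyte-enriched miR-27b at -0.99 (SE 0.36), miR-301 at -0.96 (SE 0.34), the neuronal miR-153 at -0.90 (SE 0.32) and miR-335 at -0.87 (SE 0.33). The fentanyl arrays did not behave alike. Fentanyl 1, set against control 1 of session A, gave 0.12 for miR-363-5p, 0.10 for miR-495, 0.06 for miR-103, 0.05 for miR-136 and 0.07 for miR-27b. Fentanyl 2 and 3, set against control 3 of session H, gave 1.00 for miR-103. For miR-363-5p, miR-495 and miR-27b control 3 was below background, so no difference within session H is given. Fentanyl 2 and 3 had the lowest shares of probes above background, 9.82% and 9.96%, and control 3 the weakest signal. Fentanyl 2 and 3 were not dim: their ratios of green signal to background, 30.6 and 38.2, were the highest of the hippocampus arrays. Their background thresholds were 3823 and 4872, against 654 to 1481 on the other hippocampus arrays. The low shares thus go with high thresholds, on which the labels below background also depend.

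**Figure D1:**
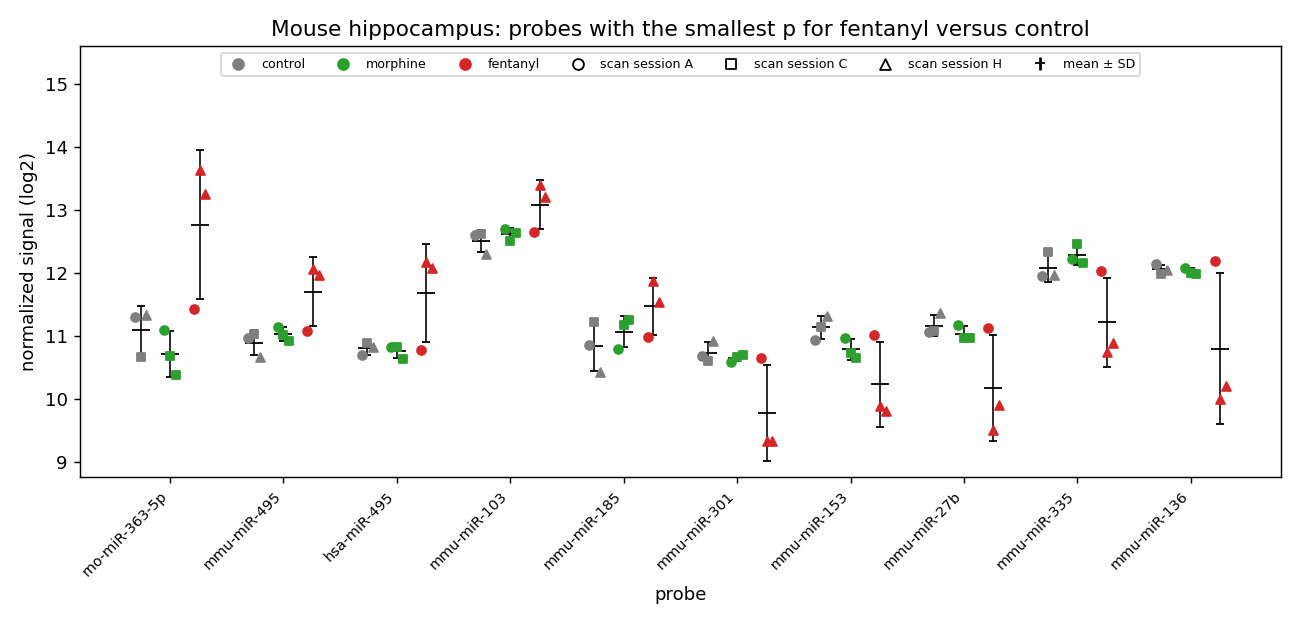
Normalized log2 signal (vertical axis) of the 10 probes with the smallest p for fentanyl versus control (horizontal axis) on the 9 hippocampus arrays; colors give the treatment, markers the scan session, and bars the mean ± SD of 3 arrays. For miR-136 the fentanyl arrays of session H lie at 10.01 and 10.22, below background, while the other 7 arrays, control 3 of session H included, lie between 11.99 and 12.19.

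limma called 0 of 133 probes for fentanyl against control in hippocampus, with 15 at an unadjusted p under 0.05 and a smallest adjusted p of 0.331. Adjusted over the list alone, 1 of the 5 miR-17-92 probes passed and none of the other lists had a probe that did, and 0 of the 8 lists were called. The count depended on fentanyl 1: without that array 37 probes were called (13 higher and 24 lower), and with array quality weights 81 (23 higher and 58 lower). With scan session as a block 0 were called (20 at an unadjusted p under 0.05), and without the arrays of session H, which leaves fentanyl 1 alone in its group, 0 (5 at an unadjusted p under 0.05).

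Fentanyl against morphine in hippocampus gave 2.05 (SE 0.50) for miR-363-5p, 0.32 within session A, and -1.06 (SE 0.33) for miR-335, which was below background on fentanyl 2 and 3, -0.20 within session A. The mouse-sequence probe of the related miR-106a gave 1.31 (SE 0.49), with 0.02 within session A, but the human-sequence probe gave -0.61 (SE 0.25) and miR-19b -0.76 (SE 0.28), both above background on 1 of the 3 fentanyl arrays. The median of all probes was -0.28, and -0.81 with the deposited values. limma called 0 of 133 probes, with 27 at an unadjusted p under 0.05 and a smallest adjusted p of 0.218, and 0 of the 8 lists. Adjusted over the list alone, 4 of the 5 miR-17-92 probes passed, 2 higher and 2 lower. Without fentanyl 1 the count was 55 (16 higher and 39 lower) and with array weights 95. With session as a block it was 0, with 2 at an unadjusted p under 0.05.

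In mouse cerebellum, 2 lists of microRNAs were called higher with morphine at the preset correlation, by small amounts, and no single probe was called. With fry neither list was called. All 5 kept probes of the miR-17-92 family were positive, with a median of 0.32, among them the human-sequence probe of miR-106a at 0.68 (SE 0.48), its mouse-sequence probe at 0.14 (SE 0.15) and miR-20b at 0.35 (SE 0.28). The list had an adjusted p of 0.00322 (adjusted p = 0.486 with an estimated correlation). Of the 6 choroid plexus and ependyma probes 5 were positive, with a median of 0.17, among them miR-34c at 0.25 (SE 0.14). The human-sequence miR-34b probe gave 0.21 (SE 0.13) and the mouse-sequence probe 0.12 (SE 0.17). The choroid plexus and ependyma list had an adjusted p of 0.00921 (adjusted p = 0.519 with an estimated correlation). The smallest p among single probes was that of the human-sequence miR-373 probe, at -0.45 (SE 0.17), with -0.30 and -0.52 in sessions B and C. As the 1 kept probe of the low-in-brain list it passed when adjusted over the list alone, which leaves its p unadjusted. limma called 0 of 175 probes, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.988. Without control 1, the value of the human-sequence miR-106a probe turned to -0.042.

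Fentanyl-treated cerebellum was represented by 1 array, so its values carry no replicate error of their own. The human-sequence probe of miR-129 was at 9.63 on that array, below background, against 10.79 ± 0.27 (SD, n = 2) in control, at least 1.56-fold lower. The human-sequence miR-520f probe was at least 1.59-fold lower and miR-744 at least 1.67-fold lower, and miR-582 was 0.65 higher (SE 0.17). Of the 11 let-7 probes 10 were negative, with a median of -0.28, among them let-7g at -0.57 (SE 0.29) and let-7b at -0.36 (SE 0.23). The let-7 list had an adjusted p of 0.0459 (adjusted p = 0.831 with an estimated correlation), which rests on that 1 array and on the assumption that it varies like the others, and its median was -0.10 with session as a block. With fry or with the replicate number as a block the list was not called. limma called 0 of 175 probes, with 7 at an unadjusted p under 0.05 and a smallest adjusted p of 0.416. Adjusted over the list alone, 1 neuronal probe and the low-in-brain probe passed, the latter as the only kept probe of its list, so that its p stayed unadjusted. With session as a block the miR-129 probe alone was called (adjusted p = 0.00766), on the same assumption, so the call cannot be assigned to the treatment.

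Against morphine, the cerebellum fentanyl array was at least 1.30-fold lower for the same miR-129 probe, below background there, and gave 0.54 (SE 0.16) for miR-582, with 0.50 in session B. The let-7 probes had a median of -0.29, 9 of 11 being negative (adjusted p = 0.0567). limma called 0 of 175 probes, with 7 at an unadjusted p under 0.05 and a smallest adjusted p of 0.783, and 0 of the 9 lists. With session as a block the miR-129 probe was called (adjusted p = 0.0266), again on 1 fentanyl array.

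Among the 13 comparisons, that between brain regions gave the most calls. Cerebellum had more miR-497 and miR-195, which share a cluster and belong to the miR-15/16 family, and less miR-137, miR-138 and miR-7, which are known from neurons. The mouse miR-497 probe was at 12.40 ± 0.10 (SD, n = 6) in cerebellum and 10.08 ± 0.40 (SD, n = 9) in hippocampus, a log2 difference of 2.26 (SE 0.16). The human-sequence probe gave 2.29 (SE 0.26). miR-195 was at 14.66 ± 0.10 (SD, n = 6) against 12.96 ± 0.23 (SD, n = 9), a difference of 1.65 (SE 0.12). miR-137 was above background on all 9 hippocampus arrays, at 12.67 ± 0.21 (SD, n = 9), and on no cerebellum array, at least 5.81-fold lower there. limma called 57 probes higher and 40 lower in cerebellum, of 186 tested, with 105 at an unadjusted p under 0.05.

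**Figure D2:**
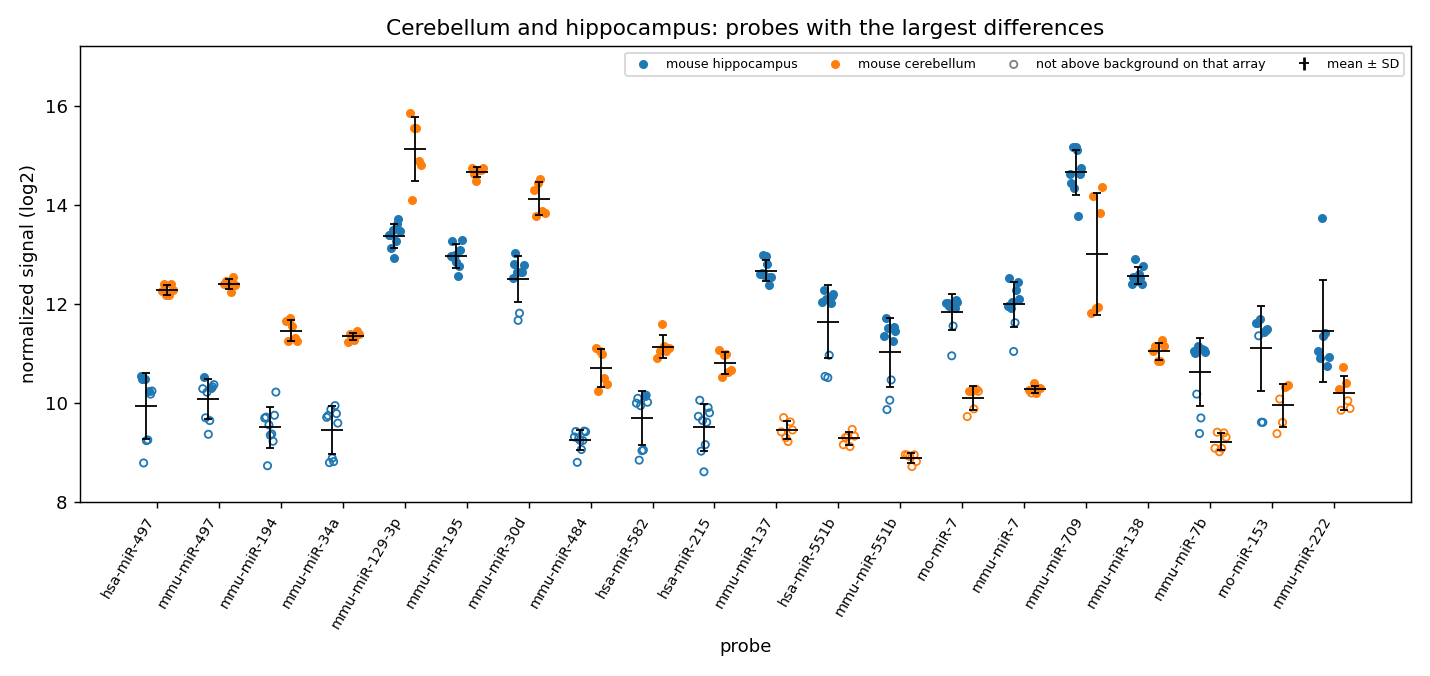
Normalized log2 signal (vertical axis) of the 10 probes with the largest rise and the 10 with the largest fall in cerebellum (horizontal axis), on 9 hippocampus and 6 cerebellum arrays; hollow points are not above background on that array and bars give the mean ± SD. The 9 hippocampus values of miR-137 are all above background and the 6 cerebellum values are all below it, while the values of miR-709 spread widely within cerebellum.

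Among the other probes higher in cerebellum, miR-194 was at least 1.54-fold and miR-34a at least 1.42-fold higher, both below background on all hippocampus arrays. miR-129-3p, another neuronal microRNA, was 1.73 higher (SE 0.24), miR-30d 1.56 (SE 0.21) and miR-582 1.39 (SE 0.23). miR-484 and miR-215 were also called, but allowed no bound on their fold against background. Among those lower in cerebellum, the mouse miR-7 probe gave -1.79 (SE 0.18) and miR-138 -1.54 (SE 0.12). The probes of miR-551b were at least 2.84-fold (human sequence) and 1.85-fold (mouse) lower, and miR-7b at least 1.41-fold lower. The rat-sequence probe of miR-153 gave -1.28 (SE 0.31), miR-709 -1.68 (SE 0.43) and miR-222 -1.22 (SE 0.40).

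Neuronal microRNAs went both ways between the regions. Of the 17 neuronal probes 10 were lower and 2 higher in cerebellum, the latter miR-129-3p and the rat-sequence miR-124a probe at 0.49 (SE 0.12). The mouse-sequence miR-124a probe gave 0.10 (SE 0.11). miR-9, needed in neural progenitors, gave -0.35 (SE 0.11) and miR-218 -0.92 (SE 0.32). The list's median was -0.38, the same with its 3 probes below background set at their bounds, and the list fell with an adjusted p of 0.000813 (adjusted p = 0.0179 with an estimated correlation). With the deposited values its median was 0.08, with 7 probes lower and 3 higher. All 12 called probes also passed when adjusted over the list alone.

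The Dlk1-Dio3 cluster, an imprinted region that encodes many brain microRNAs, was lower in cerebellum for 12 of its 25 probes and higher for 0. The 12 probes were versions of miR-376a, miR-376b, miR-369, miR-494 and miR-495 only, so they are not 12 separate microRNAs. The probes not called ranged from -0.45 (miR-434-5p) to 0.29 (rat-sequence miR-382), so a fall of the whole cluster is not shown. miR-376b (rat sequence) gave -1.09 (SE 0.17), the mouse miR-376a probe -1.05 (SE 0.17) and the human-sequence miR-494 probe -1.05 (SE 0.22). The list's median was -0.45, or -0.43 with the 4 probes below background in one region set at their bounds. Its adjusted p was 0.000657 (adjusted p = 0.471 with an estimated correlation), and 12 probes passed when adjusted over the list alone.

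Choroid plexus and ependyma microRNAs were higher in cerebellum for 4 of 6 probes, including miR-204 at 1.23 (SE 0.22) and miR-211 at 1.10 (SE 0.25). The human-sequence miR-34b probe gave 1.23 (SE 0.18), while the mouse miR-34b probe gave 0.03 (SE 0.17). The list was not called (adjusted p = 0.199), and with 75th percentile scaling 3 probes were higher and 1 lower. Both miR-451 probes, markers of red blood cells, were higher, at 0.98 (SE 0.25) and 1.08 (SE 0.28), with 0.64 and 0.62 in session C, and 1 of the 2 was called with session as a block. All 3 muscle probes were called higher, with a median of 0.73, but the 2 miR-1 probes were below background on all hippocampus arrays and set the median to 0.00 at their bounds, and 0 were called with 75th percentile scaling.

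Of the 11 let-7 probes 2 were lower, both of let-7f (-0.70, SE 0.13, and -0.61, SE 0.17), and let-7i was higher at 0.33 (SE 0.11), while with the deposited values 1 was higher and 0 lower. Astrocyte-enriched probes were lower for 3 of 10, miR-29a, miR-29b and miR-29c, and higher for 2, miR-26a and miR-21. With the deposited values 1 astrocyte-enriched probe was higher and 0 lower. miR-132, induced by neuronal activity, was called lower, by at least 1.20-fold, being below background in cerebellum. Of the 6 miR-17-92 probes 1 was lower (0 adjusted over the list alone), and of the 2 microglia and leukocyte probes 1 was higher (2 adjusted over the list alone, 0 called with 75th percentile scaling). The 13 probes linked to opioid receptors counted 2 lower and 1 higher, all of the let-7 family, and 2 passed when adjusted over the list alone. In the let-7, astrocyte-enriched, choroid plexus, red blood cell and muscle lists the counts were the same when adjusted over the list alone. Of the 2 oligodendrocyte, 3 vascular, 1 hindbrain and 1 low-in-brain probes 0 were called, and no epithelial probe was kept.

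The region differences were tested against 0, without subtracting the median of all probes. That median was 0.10, and -0.29 with 75th percentile scaling, -0.01 with cyclic loess and 0.39 with the deposited values. The numbers of probes called higher and lower may therefore shift with the scaling. Only session C held both regions. Within it miR-497 (mouse) gave 2.06, miR-195 1.47, miR-138 -1.39 and miR-7 (mouse) -2.08. miR-137 gave -2.98 within session C, but its cerebellum signal was below background, so the size is uncertain. By contrast, miR-709 gave -0.48 within session C and lost its call with session as a block (adjusted p = 0.0661). miR-222 lost its call without cerebellum control 1 or control 2.

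Whether the drug responses differed between tissues was tested as an interaction. For morphine in cerebellum against hippocampus limma called 0 of 186 probes, with 1 at an unadjusted p under 0.05. That was the human-sequence miR-373 probe at -0.99 (SE 0.44, adjusted p = 0.962). As the only kept probe of its list it also passed over the list alone, which leaves its p unadjusted. The 6 miR-17-92 probes were all positive, with a median of 0.30, and the list was called with an adjusted p of 0.0144 (adjusted p = 0.142 with an estimated correlation). With the deposited values this median was -0.05 and with session as a block 0.06, and the list was not called with fry or with the replicate number as a block.

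For morphine in rat neurons against mouse hippocampus limma called 0 of 139 probes, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.995. Of the 13 probes linked to opioid receptors 12 were negative, with a median of -0.26, among them let-7i at -0.53 (SE 0.40), let-7e at -0.54 (SE 0.44) and miR-23b at -0.20 (SE 0.32). That list was called with an adjusted p of 0.0263 (adjusted p = 0.390 with an estimated correlation), and was not called with fry or with the replicate number as a block. Most of its 13 probes belong to the let-7 family, so it is not distinct from that family, although the let-7 list itself was not called. For fentanyl, the same comparison called 0 of 139 probes, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.727, and 0 of the 8 lists. Adjusted over the list alone, 1 of the 5 miR-17-92 probes passed. miR-363-5p gave -2.26 (SE 0.74) and miR-721 1.49 (SE 0.53). The miR-363-5p probe did not pass the background filter in rat neurons, so the size of its difference is uncertain. Without hippocampus fentanyl 1 the count was 5, and with array weights 34. Species, culture and dose also differ between these systems.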

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

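Of the tests in this part, those of unspecific hybridization and those on the rat arrays numbered 3 were chosen only after the results were seen. The response to morphine differed between cerebellum and hippocampus for the miR-17-92 list, with a median interaction of 0.30 and an adjusted p of 0.0144 (adjusted p = 0.142 with an estimated correlation), and a median of -0.05 with the deposited values. The response to morphine differed between rat neurons and hippocampus for the list linked to opioid receptors, most of whose probes are of the let-7 family. The median interaction was -0.26, with an adjusted p of 0.0263 (adjusted p = 0.390 with an estimated correlation). With fry or with the replicate number as a block neither list was called.

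Probes of other species or without a microRNA name, which the comparisons did not use, gave a signal on the single array of fentanyl-treated cerebellum. Of 81 such probes 2 were called against control and 2 against morphine. The probe numbered 1545 had an amplitude of 3445 there against 395 to 836 on the other cerebellum arrays, and the miR-71 probe of worm and other invertebrate sequences 1845 against 411 to 775. These calls rest on 1 array, and a local artifact on it could not be checked, as the files used hold no spot positions.

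The fentanyl arrays 2 and 3 of hippocampus stood apart from fentanyl 1 and, within session H, from control 3: 35 of the 37 probes called without fentanyl 1 were examined, with a median change of 1.02. The intervals here resample the probes, so they do not measure the spread between arrays or animals. Fentanyl 1 minus control 1 gave a median of -0.0580 in the called direction (95% interval -0.078 to 0.014). Control 3 of session H minus morphine 2 and 3 gave 0.0912 (-0.063 to 0.221). Both lie under the limits set beforehand, which would argue against the treatment and against session H as the cause, but the limits are set aside, a decision made after the values were known, because each rests on a single array, and control 3, with the weakest signal, itself enters the calls. The treatment in those experiments and the session thus stay open and cannot be told apart on these tests. The 95th percentile of the worm-only probes, relative to the array's 75th percentile, was 1.06 higher on fentanyl 2 and 3 than on the mean of the other hippocampus arrays. The values were 1.56 and 1.53 against at most 0.68. The median amplitude of the worm-only probes did not rise likewise, at 497 and 558 against 296 to 538. Relative to the 75th percentile, 1293 and 1688 against at most 1030, that median was the lowest. A 95th percentile of the worm-only probes far above the array's 75th percentile was not particular to fentanyl 2 and 3. It was also found on the rat arrays, with 3011 against 1034 on rat control 1 and 2440 against 1252 on rat control 2. The share of probes above background on the rat arrays was 10.38% to 14.45%. Unspecific hybridization on hippocampus fentanyl 2 and 3 may contribute, as a hypothesis that rests on the brightest worm-only probes alone.

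The rat arrays numbered 3 also stood apart, 13 of 72 probes differing by more than 1 from the arrays numbered 1 and 2, among them miR-467b at -1.95, miR-744 at 1.63, miR-125b at -1.47 and miR-711 at 1.34. Fentanyl 3, scanned in session F, deviated by -1.66 for miR-125b but by -0.20 for miR-467b, against -1.38 and -2.82 on control 3 and morphine 3 of session G. Across probes, which are not independent replicates, the deviations correlated with r = 0.449 (95% interval 0.255 to 0.599), but fentanyl 3 is 1 array, so 1 scan session alone stays open. A larger share of astrocytes in those cultures could not be decided: the 8 astrocyte-enriched probes exceeded the 8 neuronal ones by 0.305 in the median (-0.207 to 0.812, an interval over probes). The experiment itself, on another day and with other animals, stays open as untested.

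Other splits of the arrays bear on whether chance can be excluded. For the region comparison 1 of 100 splits, the real one, gave as many calls (97, against at most 35), which argues against a chance division of the arrays. As only session C held both regions, these splits cannot separate region from session. For the 6 drug comparisons in rat neurons and hippocampus the 10 splits of 3 against 3 are too few for a share under 0.05, and the real value was 0. The highest of the other splits was 0, except for fentanyl against control in hippocampus, where the split of control 1, control 2 and fentanyl 1 against the 3 arrays of session H gave 68, which points to a structure of the samples, and with session as a block the real value was 0. For the morphine and fentanyl responses of rat neurons against hippocampus the real value was 0, so that all 100 of 100 splits gave as many by construction and decide nothing on chance. The highest of the others were 57 and 61, which again points to a structure of the samples.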

How the results depend on the processing

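The number of arrays and the signal limit these results: the signal exceeded background for 9.82% to 23.7% of the probes of an array. On simulated data the share of probes recovered at a log2 change of 1 and of 2 was 52% and 85% for morphine and 60% and 82% for fentanyl in rat neurons (71 probes), 51% and 94% and 48% and 95% in hippocampus (130 probes), 66% and 91% and 43% and 79% in cerebellum (175 probes), and 85% and 99% between the regions (180 probes). For fentanyl against morphine it was 61% and 92% in rat neurons, 55% and 93% in hippocampus and 66% and 90% in cerebellum. It was lower for the interactions: 29% and 67% for morphine in cerebellum against hippocampus (180 probes), and 20% and 66% for morphine and 17% and 64% for fentanyl in rat neurons against hippocampus (134 probes). Plain background subtraction was not run, for lack of background columns, and neither was the green over red ratio, for which 0 or 1 probe had red signal on all arrays. The cause of the changes below was not tested, unless named.

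Of the named region probes, 516 values under alternatives kept direction and call, 6 of miR-709 and miR-222 lost the call, and none reversed. The region count stayed between 70 and 102 when single arrays were left out, and was 28 with the filter on every array, where only 57 probes were tested. Of the other named probes 2459 values kept their side of the threshold, 54 passed it and 19 reversed. Without single arrays, the counts ranged from 0 to 37 for fentanyl against control in hippocampus, 0 to 55 for fentanyl against morphine, and 0 to 5 for the fentanyl interaction. These maxima came without fentanyl 1, and each other count of 0 stayed 0. Array weights gave 81, 95 and 34. In cerebellum, fentanyl against control gave 1 with the number block and 1 with the session block, and fentanyl against morphine 1 without the dim-probe filter and 1 with the session block.

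List calls went to 0 with an estimated correlation and with fry for cerebellum morphine, cerebellum fentanyl and both morphine interactions, and to 1 and 4 for the regions. With 75th percentile scaling they were 2 for hippocampus morphine, 1 for cerebellum fentanyl against morphine, 3 for the morphine interaction of cerebellum and 2 for that of rat neurons. With the number block they were 0 for cerebellum fentanyl and both morphine interactions.

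Reversed with the deposited values were, in rat fentanyl, miR-29b (0.068) and miR-29a (0.064); in hippocampus morphine, miR-29a (0.16), miR-691 (0.11), miR-29c (0.17) and miR-320 (0.072); in the cerebellum morphine interaction, let-7f (-0.12); and in the rat morphine interaction, miR-29a (-0.091) and miR-137 (-0.25). Without session H, which leaves 1 hippocampus fentanyl array, assumed to vary like the others, hippocampus fentanyl reversed for hsa-miR-495 (-0.0086), miR-185 (-0.067), miR-301 (0.012), miR-27b (0.075) and miR-136 (0.14), and the fentanyl interaction for hsa-miR-495 (0.012). Rat fentanyl miR-23a was -0.036 with 75th percentile scaling. Without single arrays, rat morphine miR-744 ranged from -1.07 to 0.21 (without control 3), and hsa-miR-106a from -0.042 (without cerebellum control 1) to 1.36 for cerebellum morphine and from -0.089 (the same) to 1.16 for its interaction.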

Other observations

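Cultured rat neurons and mouse hippocampus were compared only after the data were seen, over 9 arrays each and 139 probes. Several markers of cells other than neurons were low in the cultures. The oligodendrocyte miR-219 was at least 2.06-fold lower and miR-338 at least 2.82-fold lower, the red blood cell miR-451 at least 2.30-fold and the endothelial miR-126-3p at least 1.71-fold lower, all 4 below background on every rat array. Both oligodendrocyte, both erythroid and all 3 vascular probes were called lower, also with 75th percentile scaling. Of 10 astrocyte-enriched probes 7 were lower and 1, miR-21 at 1.42 (SE 0.21), was higher. Of 5 choroid plexus and ependyma probes 2 were higher and 0 lower, with a median of 0.40. Of 16 neuronal probes 11 were lower, such as miR-218 at -2.28 (SE 0.34), and 2 higher, such as miR-9 at 1.21 (SE 0.14).

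Higher in the cultures were miR-711, at least 8.09-fold, miR-674*, at least 2.87-fold, and miR-184, at least 1.64-fold, each below background on all hippocampus arrays, and miR-206, a muscle marker, at 2.67 (SE 0.17). In all, 28 probes were higher and 61 lower, with a median of -0.31. With 75th percentile scaling these were 28 and 54 with a median of -0.21, and with cyclic loess 36 and 57 with a median of -0.25. Of 100 splits of the 18 arrays 1, the real one, gave as many calls (89, against at most 3). Species, age, culture and scan session all differ between the sets, so the difference cannot be assigned to any of them.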
